A study of Mus musculus with 15 samples.

How the data were processed

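Total RNA from whole pancreas of male C57BL/6J mice was labelled with Cy3 and hybridised to Agilent one-colour arrays, 1 array per animal, and the labels number the animals separately, so that no animal is shared between groups. The 15 arrays fall into 4 groups: 4 wild type (WT) mice and 3 transgenic (TG) mice given saline, and 4 wild type and 4 transgenic mice given cerulein, a cholecystokinin analogue that elicits acute pancreatitis in rodents. Per the labels, mice fasted for 18 h, received 1 intraperitoneal injection of 50 µg/kg cerulein in saline or saline alone, and were killed 3 h later; the saline groups carry a time label of 0 h. The series text gives 4 animals per group, and 3 transgenic saline arrays were deposited.

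The values are spot signals in units of fluorescence intensity, which the authors obtained with Agilent Feature Extraction 10.7.3.1 per the file headers. That program subtracted background and removed spatial trends within each array and made no adjustment between arrays. The flag columns, a unit of their own (other: 0 or 1 for each spot), are deposited beside the signals. The deposited series table gives log2 values that the authors normalised between arrays by a method not given in the sources used here. It holds 42482 probes, of which 42379 occur in the scanner output. Its columns correlated with log2 signal of the same array at r = 0.987 to 0.998 across probes, with slopes of 0.998 to 0.999 among bright probes and column medians of 6.56 to 6.93, so its scale is log2 and it is not centred per gene, while the method behind the offset between arrays stays unknown. It was used only as an alternative.

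Of 59305 non-control spots per array, spots of the same probe were averaged to 55681 probes. No probe was saturated on any array, and 105 to 188 spots per array carried an outlier flag and were left out. Among kept genes, 21 probes had no unflagged spot on at least 1 array. The scanner output names probes by accession only. Accessions were matched without their version to a RefSeq table, which named 27235 probes by 1 symbol each and left 28446 without one. None matched several symbols. Of 27752 probes with a RefSeq transcript accession, 27220 were matched, and 20660 genes had a probe. No probe positions are given. Log2 processed signal minus the array's 75th percentile was used throughout. A probe was kept when it was well above background on at least 3 arrays, which left 42181 probes, 22389 of them with a symbol, and 17338 genes, each read from its brightest kept probe. The precision is limited by the number of arrays.

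Groups were compared with limma 3.58.1 in R 4.3.3 (tables read with the data.table package, version 1.17.8), by lmFit and eBayes with default settings on the 4 group means of all 15 arrays, with no covariate. This leaves 11 residual degrees of freedom, and eBayes added 3.54 prior ones. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over genes within each of the 5 comparisons, and a gene was called at an adjusted p below 0.05. The 5 comparisons are cerulein against saline in each genotype, transgenic against wild type after each treatment, and the difference between the genotypes' cerulein responses. The 26 gene lists, with 482 names of which 471 are on the array and 453 were measured, were tested with camera at a preset inter-gene correlation of 0.01 and again with a correlation estimated from the residuals. Adjustment was over the 26 lists within each comparison. The lists, the tests, the rule for named genes and most of the other settings tried were fixed before the data were examined. Errors of differences are standard errors from limma, and errors of group means are standard deviations.

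The lists cover digestive enzymes and other acinar secretory products, acinar transcription factors, duct and acinar-to-ductal metaplasia markers, immediate early genes, cytokines and NF-kB targets, ER stress genes, heat shock proteins, ERBB ligands and receptors with ERK feedback genes, Reg family and acute phase genes, antioxidant genes, autophagy genes, ribosome biogenesis, YAP and SRF targets, sterol synthesis, cell cycle, p53 targets and the circadian clock. The others are markers of neutrophils, macrophages, lymphocytes, islet cells, adipocytes, fibroblasts and stellate cells, endothelium, erythrocytes and intestinal epithelium. Named genes are, in each comparison, the 6 highest and 6 lowest called genes with an official symbol whose groups do not overlap, or all called genes if there are 12 or fewer. To these are added the 2 called members with the largest change of each of the first 10 lists, the called members of the other lists where there are 5 or fewer (otherwise the 2 with the largest change), and Btc, Egfr, Erbb2, Erbb3 and Erbb4. Not every gene that the rule names is described, and results for 2 of them are not reported here. Other genes named were chosen after their values were seen, which is said where they appear.

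The arrays lie on 3 slides scanned on 2 days. Slide 1 holds all 4 groups, slide 2 holds 1 transgenic and 2 wild type cerulein arrays and no saline array, and slide 3 holds all 4 groups and was the only slide scanned on the second day. Each difference was therefore also estimated with slide as a fixed block, called slide-adjusted here, which leaves 9 residual degrees of freedom, and within single slides. Where a group had no array well above background, a fold is printed as "at least", computed against the lowest signal called well above background on each of those arrays; the log2 difference beside it is the fitted value and no bound. In a test on simulated data, 200 of 17317 genes were given changes of 1 or 2 on the log2 scale. Noise was drawn independently for each gene, whereas genes of the real arrays vary together, so real false calls may be more numerous. Without a slide term 69% of changes of 2 were called in the wild type cerulein comparison, 76% in the transgenic one, 79% between genotypes after saline and 77% after cerulein; of changes of 1, the shares were 26%, 14%, 9% and 10%. False calls numbered 4, 0, 0 and 2. With slide as a fixed block 77%, 88%, 89% and 89% of changes of 2 and 52%, 45%, 53% and 52% of changes of 1 were called, with 11, 6, 8 and 10 false calls.

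Alternatives were normexp with an offset of 50, quantile normalization, no filter on dim probes, only probes above background on all 15 arrays, slide as a fixed block, slide as a random block (correlation 0.667), single slides, the series table, the mean of a gene's probes, eBayes with trend and robust, array weights, only the groups compared, and leaving out each array in turn. Chosen after the data were seen were normexp on the median rather than the mean signal, which the files lack, all features including those without a symbol, and a fit without slide 2. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.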

Results

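Messenger RNA was measured in whole pancreas of wild type and transgenic mice 3 h after saline or a single dose of cerulein. The series title ties the transgenic mice to betacellulin (Btc), a ligand of the EGFR and ERBB4 receptors, and to ERBB4 in acute pancreatitis. There were 4 wild type saline, 4 wild type cerulein, 3 transgenic saline and 4 transgenic cerulein arrays. Between 54.9% and 76% of probes were well above background on an array, with 54.9% to 65.3% in the wild type saline group, 60.1% to 68.2% in the transgenic saline group, 65.1% to 76% in the wild type cerulein group and 63.8% to 74.7% in the transgenic cerulein group. The 75th percentile of signal ranged from 152 to 529 intensity units. Expression profiles of animals of the same group on the same slide correlated across genes at a median r of 0.978 (6 pairs), and those of the same group on other slides at 0.957 (15 pairs). Across genes, whose values are not independent, different groups on the same slide gave 0.959 (28 pairs).

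The leading principal component held 40.4% of the variance. Of its variance, 91.1% lay between slides, 53.6% between treatments and 1.8% between genotypes. The second component held 21%, of which 44.9% lay between treatments and 10.2% between genotypes.

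**Figure D1:**
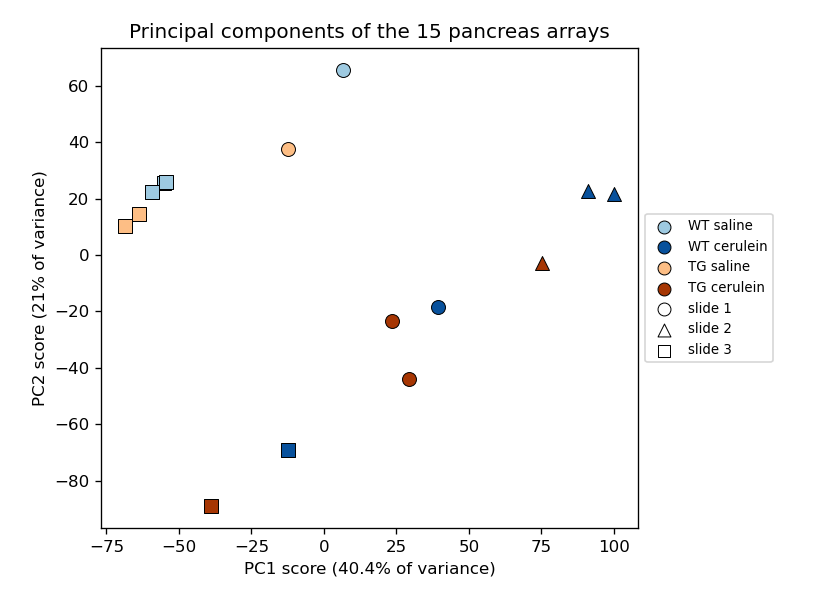
Scores of the 15 arrays on the first (x axis, 40.4% of variance) and second (y axis, 21% of variance) principal components of log2 signal, coloured by group and shaped by slide. Arrays of slide 3 lie to the left and the 3 cerulein arrays of slide 2 to the right, and within slides 1 and 3 cerulein arrays lie below saline arrays.

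The first comparison asks how the wild type pancreas responded to cerulein. Atf3, a stress-induced transcription factor, rose 948-fold (log2 9.89 ± 0.29 SE, adjusted p = 5.11e-11, n = 4 and 4), from a saline level that was well above background on 2 of 4 arrays. Kel, a membrane metalloprotease, rose by 7.63 ± 0.45, Rcan1, a regulator of calcineurin, by 6.43 ± 0.39, Chac1, a glutathione-degrading enzyme, by 6.07 ± 0.65, and the growth arrest gene Gadd45a by 5.84 ± 0.33. Tac1, which encodes the precursor of substance P, rose at least 15.2-fold (6.05 ± 0.99, adjusted p = 0.00105). Decreases included those of Sostdc1, a secreted antagonist of BMP and WNT signals (-4.08 ± 0.39), Rab3a, a GTPase of regulated exocytosis (-3.8 ± 0.3), N4bp2l1 (-3.72 ± 0.42), Ypel2 (-3.65 ± 0.41) and the kinase gene Plk2 (-3.42 ± 0.34). Stxbp5, a SNARE-binding protein, fell at least 2.61-fold (fitted log2 -3.52 ± 0.5). In all 12 genes every cerulein array lay beyond every saline array, and all 12 calls held when each array was left out in turn. Slide-adjusted differences were 10.27 for Atf3, 8.01 for Kel, -4.36 for Sostdc1 and -3.27 for Rab3a. Within slides 1 and 3 Atf3 differed by 10.1 and 10.57, Sostdc1 by -3.62 and -5.33.

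In total 976 genes rose and 1448 fell, of 17338 tested, and 796 and 903 of them changed at least 2-fold. With slide in the model 2387 rose and 1351 fell; of the genes called without it, 912 of those that rose and 1039 of those that fell were called again the same way. Within slides 1 and 3 the sign was the same on both slides for 970 and 1419 of them. Genes that rose made up 40.3% of calls, 29.2% with normexp background correction and 63.9% with slide in the model, and the median of all genes moved from -0.06 to -0.23 with normexp. The count of lowered genes fell to 657, 687 and 751 without saline replicates 6, 7 and 8, to 726 and 773 without cerulein replicates 12 and 11, and rose to 3181 without cerulein replicate 10. Of 604 called genes with several probes, 144 had a probe with the opposite sign.

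Immediate early genes, transcribed within minutes to hours of a stimulus, rose as a group in wild type mice (median 2.48, adjusted p = 1.83e-21; adjusted p = 0.0338 with an estimated correlation). Of 29 measured members, 20 rose and 1 fell, or 23 and 1 adjusted over the list alone, led by Atf3 and Gadd45a. The slide-adjusted median was 2.81, and the medians within slides 1 and 3 were 2.43 and 3.31. Targets of YAP and SRF, regulators that respond to the cytoskeleton, rose (median 1.32, adjusted p = 2.34e-10; adjusted p = 0.234 with an estimated correlation), with 10 of 15 members up (11 adjusted over the list alone). Ccn1 rose by 4.36 ± 0.43 and Ankrd1 by 4.26 ± 0.6. With slide in the model the median was 1.72, with 1.53 and 2.17 within slides 1 and 3.

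Cytokines, chemokines and NF-kB targets rose in wild type mice (median 0.69, adjusted p = 3.29e-05; adjusted p = 0.234 with an estimated correlation), with 5 of 28 members up (8 adjusted over the list alone). The neutrophil and monocyte attractants Ccl7 (at least 15-fold, 5.38 ± 0.4) and Cxcl1 (at least 5.16-fold, 4.17 ± 0.27) were not above background in any saline array. The slide-adjusted median was 0.52, within slides 1 and 3 it was 0.69 and 0.59, and with normexp it was 0.01, still called. Heat shock proteins rose (median 0.6, adjusted p = 0.00022; adjusted p = 0.509 with an estimated correlation), with 6 of 14 members up and none down, or 6 up and 1 down adjusted over the list alone. Hspa1a, the inducible HSP70, rose by 4.6 ± 0.93 and Hspa4l by 3.94 ± 0.37, and the slide-adjusted median was 1.24 (1.62 and 1.55 within slides 1 and 3). Of 16 sterol synthesis genes 5 rose (5 adjusted over the list alone; median 0.54, adjusted p = 0.00155; slide-adjusted 0.77, within slides 0.73 and 0.87). Srebf2, a transcription factor that activates sterol synthesis genes, rose by 1.22 ± 0.25; its other probe gave 0.31, and the call was lost with normexp. Of 13 p53 targets 4 rose and 1 fell (6 and 1 adjusted over the list alone; median 0.2, adjusted p = 0.0107; slide-adjusted 0.47, within slides 0.46 and 0.52). Trp53inp1 rose by 3.93 ± 0.41, the cell cycle inhibitor Cdkn1a by 3.45 ± 0.3, Plk3 by 3.06 ± 0.33 and the pro-apoptotic Bbc3 by 2.1 ± 0.27, and Plk2 fell. The other Cdkn1a probe gave 0.27. The sterol and p53 lists gave adjusted p = 0.509 with an estimated correlation.

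Relative to the array's 75th percentile, digestive enzymes and other acinar secretory products fell in wild type mice (median -0.78, adjusted p = 2.19e-06, and 0.509 with an estimated correlation). The mean level of the list was lower on wild type arrays where that percentile was higher. Saline replicate 6 had a list mean of 10.56 and a log2 percentile of 7.25, and cerulein replicate 11 had 9.18 and 8.68. A fall of these transcripts therefore cannot be told from the scaling to the percentile. Of 29 members 2 were called down over all genes and 27 adjusted over the list alone, among them Rnase1 (-1.21 ± 0.28). Adjusted for slide, the median was -0.24, with -0.31 and -0.19 within slides 1 and 3, and with quantile normalization the median was -0.01 and the list was not called. Acinar transcription factors had a median of -0.75 (adjusted p = 0.0565, slide-adjusted -0.35, within slides -0.53 and -0.36). Of 11 members 3 fell and 1 rose (7 and 2 adjusted over the list alone). Foxa2 fell by 2.65 ± 0.3 and Rbpjl, a subunit of the acinar PTF1 complex, by 1.81 ± 0.28; Ptf1a itself, chosen after its values were seen, rose by 1.17. Duct and acinar-to-ductal metaplasia markers rose as a list (median 0.38, adjusted p = 0.0258; adjusted p = 0.509 with an estimated correlation), with 5 of 18 up and 3 down (6 and 3 adjusted over the list alone). The keratin genes Krt8 and Krt20 rose by 4.21 ± 0.36 and 2.88 ± 0.62, whereas Onecut1 and Sox9, duct transcription factors chosen after their values were seen, fell by 1.7 and 1.68. The slide-adjusted median was 0.55 (1.03 and 0.54 within slides 1 and 3), and the list was not called without saline replicate 5 or cerulein replicate 10, with medians from 0.26 to 0.5 over all such fits.

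Genes of ER stress moved in opposite directions in wild type mice, so that the list had a median of -1.03, a mean of 0.01 and a test that was not called (adjusted p = 0.149; slide-adjusted median -0.52, within slides -0.38 and -0.75). Of 23 members 5 rose and 10 fell (5 and 13 adjusted over the list alone), and 8 rose and 9 fell with slide in the model. Without it Chac1, Trib3 (5.58 ± 0.47) and, chosen after their values were seen, Ddit3 (2.27), Ppp1r15a (2.37) and Atf4 (1.78) rose, all genes of the integrated stress response. Among those that fell were, also chosen afterwards, Sel1l (-2.31), Dnajc3 (-1.59), Pdia4 (-1.59) and Calr (-1.51), which encode chaperones and degradation factors of the ER. This grouping was made after the values were seen and was not tested. Antioxidant genes had a median of -0.19, a mean of 0.13 and adjusted p = 0.759, with 3 of 15 up and 2 down (3 and 3 adjusted over the list alone; slide-adjusted median 0.21, within slides 0.26 and 0.39). Srxn1, which restores peroxiredoxins, rose by 3.11 ± 0.36, and the cystine transporter Slc7a11 by 2.56 ± 0.64, a call lost without saline replicate 8 (highest adjusted p over such fits 0.057).

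Among ERBB ligands, receptors and ERK feedback genes 5 of 23 rose and 4 fell in wild type mice (6 and 5 adjusted over the list alone; median 0.24, adjusted p = 0.0999; slide-adjusted 0.24, within slides 0.26 and 0.1). Hbegf, a ligand of EGFR and ERBB4, rose by 5.6 ± 0.3, the ERK phosphatase Dusp5 by 2.62 ± 0.38, Egfr by 2.51 ± 0.37 (adjusted p = 0.000471) and Erbb3 by 1.55 ± 0.33 (adjusted p = 0.00663). With normexp the Dusp5 and Erbb3 calls were lost. The other Egfr probes gave 0.5 and 0.85. Btc rose by 1.55 ± 0.45 (adjusted p = 0.0331), with every cerulein array above every saline array and 1 of 4 saline arrays well above background. Its call was lost without saline replicate 7 or 8 or cerulein replicate 9 or 10, with a lowest difference of 1.17, and with normexp, quantile normalization, the series table or array weights. Slide-adjusted differences were 1.9 for Btc (adjusted p = 0.0233; 1.36 and 2.68 within slides), 3.01 for Egfr (3.55 and 3.16) and 1.82 for Erbb3 (0.84 and 2.34). Erbb2 differed by 0.34 ± 0.28 (adjusted p = 0.421, slide-adjusted 0.03), and Erbb4 was above background on 1 of 15 arrays and was not tested.

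Of the other groups in wild type mice, 3 of 21 Reg family and acute phase genes rose (3 adjusted over the list alone; median 0.53, adjusted p = 0.0371; adjusted p = 0.436 with an estimated correlation). Lcn2, an iron-siderophore binding protein, rose by 1.28 ± 0.26. With slide as a block the median was 0.41 and not called (0.41 and 0.35 within slides), it was -0.04 with normexp, and the call was lost without saline replicate 6 or 8 or cerulein replicate 10 or 11 (lowest 0.37). Neutrophil markers rose (median 0.44, adjusted p = 0.0371; adjusted p = 0.509 with an estimated correlation), with 4 of 12 up (4 adjusted over the list alone), among them Clec4d (2.49 ± 0.41). Their median was 0.51 and not called with slide in the model (0.23 and 0.94 within slides), -0.27 with normexp and -0.53 among probes above background on all arrays. The call was lost without saline replicate 5 or cerulein replicate 10 (lowest 0.29). S100a9, a calcium-binding protein of neutrophils, rose by 2.85 ± 0.71 with overlapping groups, a call lost without saline replicate 7 or 8 (lowest 2.39). Islet markers fell (median -0.63, adjusted p = 0.0107; adjusted p = 0.509 with an estimated correlation), 3 of 20 members being called down (3 adjusted over the list alone). The slide-adjusted islet median was -0.19 and not called (-0.1 and -0.25 within slides). Adipocyte markers fell (median -0.84, adjusted p = 0.0285; adjusted p = 0.509 with an estimated correlation; slide-adjusted -0.8, within slides -1.13 and -0.37). Of 13 members 3 fell (6 adjusted over the list alone), among them the receptor gene Acvr1c (-3.15 ± 0.37), and the list was not called without saline replicate 5 or cerulein replicate 10 (range -1.15 to -0.51).

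The remaining lists were not called in wild type mice. Ribosome biogenesis had a median of 0.18 (adjusted p = 0.0553, slide-adjusted 0.56 and called), and 4 of 21 members rose, Nop58 by 1.64 ± 0.34 and Rrp12 by 1.29 ± 0.22. This list was also called with normexp, quantile normalization, no filter, the filter on all arrays, the series table and without slide 2. Circadian clock genes had a median of 0.26 (adjusted p = 0.118), with 3 of 16 up and 2 down, among them Ciart (4.63 ± 0.66) and Bhlhe40 (1.46 ± 0.2), both transcriptional repressors. The medians were -0.28 for autophagy genes (adjusted p = 0.733), -0.1 for cell cycle genes (0.718), -0.04 for macrophage markers (0.718) and -0.09 for lymphocyte markers (0.759). Camera gave the direction of the macrophage and lymphocyte lists as up, although their medians were negative. The other medians were -0.39 for fibroblast markers (adjusted p = 0.0896), -0.42 for endothelial markers (0.0736), 0.14 for erythrocyte markers (0.55) and 0.59 for intestinal markers (0.0766). Within the lists not called, the monocyte receptor Cd14 rose by 1.36 ± 0.19 and Vil1, an actin-bundling protein of brush borders, by 2.53 ± 0.46.

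The second comparison asks how the transgenic pancreas responded to cerulein (n = 4 and 3). Atf3 rose 860-fold (9.75 ± 0.31, adjusted p = 1.9e-10), with 2 of 3 saline arrays above background. Kel rose by 7.1 ± 0.49, Rcan1 by 6.8 ± 0.42, Chac1 by 6.26 ± 0.7, Tac1 by 6.01 ± 1.07 (1 of 3 saline arrays above background) and Hbegf by 5.95 ± 0.33. Sostdc1 fell by 3.63 ± 0.42, Grpr, the receptor of gastrin-releasing peptide, by 3.29 ± 0.59, N4bp2l1 by 3.05 ± 0.46 and Rab3a by 3.04 ± 0.33. Spinkl fell at least 3.45-fold (fitted log2 -3.88 ± 1) and Fam81a at least 2.35-fold (fitted log2 -3.27 ± 0.42). In all 12 genes every cerulein array lay beyond every saline array. The Spinkl call was lost without saline replicate 2 or 3 or cerulein replicate 14 or 16 (range -5.57 to -3). Slide-adjusted differences were 10.02 for Atf3, 7.37 for Kel, -3.81 for Sostdc1 and -2.7 for Rab3a. Within slides 1 and 3 Atf3 differed by 10.25 and 9.64, Sostdc1 by -3.09 and -4.12.

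In transgenic mice 829 genes rose and 593 fell, 745 and 454 of them at least 2-fold. With slide in the model 2635 rose and 1447 fell, and 829 and 588 of the calls made without it were among them. Within slides 1 and 3 the sign was the same for 828 and 593. Raised genes were 58.3% of calls, and the median of all genes moved from -0.06 to -0.2 with normexp. Without saline replicate 3 the counts were 509 and 186, without saline replicate 4 they were 547 and 202, and the lowered genes numbered 289 and 360 without cerulein replicates 14 and 16. Of 360 called genes with several probes, 60 had a probe with the opposite sign.

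Immediate early genes rose in transgenic mice (median 2.44, adjusted p = 5.86e-25; adjusted p = 0.0193 with an estimated correlation), with 21 of 29 up (22 up and 1 down adjusted over the list alone). Their slide-adjusted median was 2.72, with 2.41 and 2.45 within slides 1 and 3. Across all comparisons only the immediate early list in the 2 cerulein responses held with an estimated correlation. YAP and SRF targets rose (median 1.34, adjusted p = 4.56e-11; adjusted p = 0.2 with an estimated correlation; slide-adjusted 1.59, within slides 1.33 and 1.86). Of 15 members 10 rose (11 up and 1 down adjusted over the list alone), Ccn1 by 4.12 ± 0.46 and the tropomyosin gene Tpm4 by 3.44 ± 0.37. Heat shock proteins rose (median 1.22, adjusted p = 2.54e-07; adjusted p = 0.434 with an estimated correlation; slide-adjusted 1.71, within slides 1.56 and 1.42). Of 14 members 6 rose (7 up and 1 down adjusted over the list alone), among them Hspa4l (4.34 ± 0.4). Cytokines, chemokines and NF-kB targets rose (median 0.62, adjusted p = 6.18e-07; adjusted p = 0.152 with an estimated correlation; slide-adjusted 0.59, within slides 0.28 and 0.95, 0.11 and called with normexp). Of 28 members 8 rose (10 adjusted over the list alone), Ccl7 at least 15.2-fold (4.84 ± 0.44) and Cxcl1 at least 6.71-fold (4.74 ± 0.29).

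Ribosome biogenesis genes rose in transgenic mice (median 0.54, adjusted p = 5.28e-06; adjusted p = 0.555 with an estimated correlation; slide-adjusted 0.76, within slides 0.63 and 0.86). Of 21 members 5 rose (8 adjusted over the list alone), Nop58 by 2 ± 0.37 and Ddx21 by 1.58 ± 0.3. The other Ddx21 probe gave 0.31, and the call was lost with the mean of the probes. Sterol synthesis genes rose (median 0.57, adjusted p = 1.84e-05; adjusted p = 0.422 with an estimated correlation; slide-adjusted 0.81, within slides 0.47 and 1.25), with 5 of 16 up (7 adjusted over the list alone), Srebf2 by 1.44 ± 0.27 (0.4 by its other probe). Of 13 p53 targets 4 rose and 1 fell (5 and 1 adjusted over the list alone; median 0.53, adjusted p = 0.00255; adjusted p = 0.434 with an estimated correlation; slide-adjusted 0.57, within slides 0.41 and 0.63). Cdkn1a rose by 3.44 ± 0.32 (0.58 by its other probe) and Plk2 fell by 2.87 ± 0.37. Duct markers rose (median 0.38, adjusted p = 0.013; adjusted p = 0.608 with an estimated correlation; slide-adjusted 0.52, within slides 0.07 and 0.76), with 4 of 18 up and 2 down (5 and 2 adjusted over the list alone). Krt8 rose by 4.26 ± 0.39 and Onecut1 fell at least 1.99-fold (-2.61 ± 0.55).

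Relative to the 75th percentile, digestive enzymes fell as a group in transgenic mice (median -0.7, adjusted p = 2.04e-06, and 0.63 with an estimated correlation). However, 0 of 29 members passed limma's test over all genes or adjusted over the list alone. As in wild type mice, the fall follows the scaling and is no evidence that these transcripts fell. Saline replicate 3 had a list mean of 10.26 and a log2 percentile of 7.48, and cerulein replicate 16 had 8.89 and 9.05. Limma called 8 members lower with slide in the model. The slide-adjusted median was -0.35 (-0.17 and -0.5 within slides 1 and 3), and with quantile normalization it was -0.04 and not called. Islet markers fell (median -0.45, adjusted p = 0.014; adjusted p = 0.677 with an estimated correlation) with 0 of 20 members called. Their median was -0.18 and not called with slide in the model (-0.46 and -0.03 within slides), and without cerulein replicate 16 the list was not called (-0.35). Acinar transcription factors had a median of -0.74 (adjusted p = 0.137), with Foxa2 (-2.38 ± 0.32) and Rbpjl (-1.73 ± 0.3) down; 3 of 11 members fell and 2 rose. ER stress genes had a median of -0.46, a mean of 0.46 and adjusted p = 0.626, with 5 of 23 up, Chac1 and Trib3 (5.55 ± 0.51) among them, and 1 down. Reg family and acute phase genes had a median of 0.01, a mean of -0.15 and adjusted p = 0.847. Reg3g, a secreted antibacterial lectin, fell by 2.95 ± 0.79 (slide-adjusted -3.14), a call lost without any of the saline replicates 2, 3 and 4 or without cerulein replicate 14 or 16 (range -3.45 to -2.4). Antioxidant genes had a median of 0.06 (adjusted p = 0.125), with 3 of 15 up, Slc7a11 by 4.12 ± 0.69 and Srxn1 by 3.03 ± 0.39. With slide in the model camera called the list (median 0.28, adjusted p = 0.0365). It was also called with normexp, with quantile normalization and without slide 2.

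In the ERBB list 3 of 23 members rose and 1 fell in transgenic mice (5 and 2 adjusted over the list alone; median 0.09, adjusted p = 0.0553). Egfr rose by 2.79 ± 0.4 (adjusted p = 0.000509; slide-adjusted 3.16, within slides 2.58 and 3.28), and its other probes gave 0.55 and 0.81. Btc differed by 1.48 ± 0.48 (adjusted p = 0.0748), with all 4 cerulein arrays above all 3 saline arrays, and was called with slide in the model (1.72, adjusted p = 0.0321; within slides 0.96 and 2.13). Erbb3 differed by 0.93 ± 0.36 (adjusted p = 0.138, slide-adjusted 1.06) and Erbb2 by 0.08 ± 0.31 (adjusted p = 0.904, slide-adjusted -0.18). The other lists were not called. Their medians were -0.13 for autophagy genes, with a mean of 0.05, -0.24 for cell cycle genes, 0.12 for clock genes, 0.25 for neutrophil, -0.02 for macrophage (mean 0.03), -0.61 for lymphocyte, -0.5 for adipocyte, 0.01 for fibroblast, -0.3 for endothelial, 0.21 for erythrocyte and -0.05 for intestinal markers (mean 0.14). With slide in the model camera called adipocyte markers lower, as in wild type mice (-0.54, adjusted p = 0.0448), and it did so without slide 2.

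The third question is whether the responses differed between genotypes. They ran in parallel: 701 genes rose in both genotypes, against 46.7 if calls were independent, 510 fell in both, against 49.5, and 0 were called in opposite directions by limma. Of 2635 genes called in either genotype, 2619 (99.4%) had the same sign in both. Across genes, which are not independent replicates, the log2 changes correlated at r = 0.852 (Spearman's rho 0.823). With slide in the model 2100 rose in both, against 363 if calls were independent, and 847 fell in both, against 113, and r was 0.871. The calls of the 2 genotypes share each gene's estimate of spread. Without slide in the model they also share slide 2, which holds cerulein arrays of both genotypes and no saline array. The calls are therefore not fully independent, and part of the overlap could arise without a shared response.

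**Figure D2:**
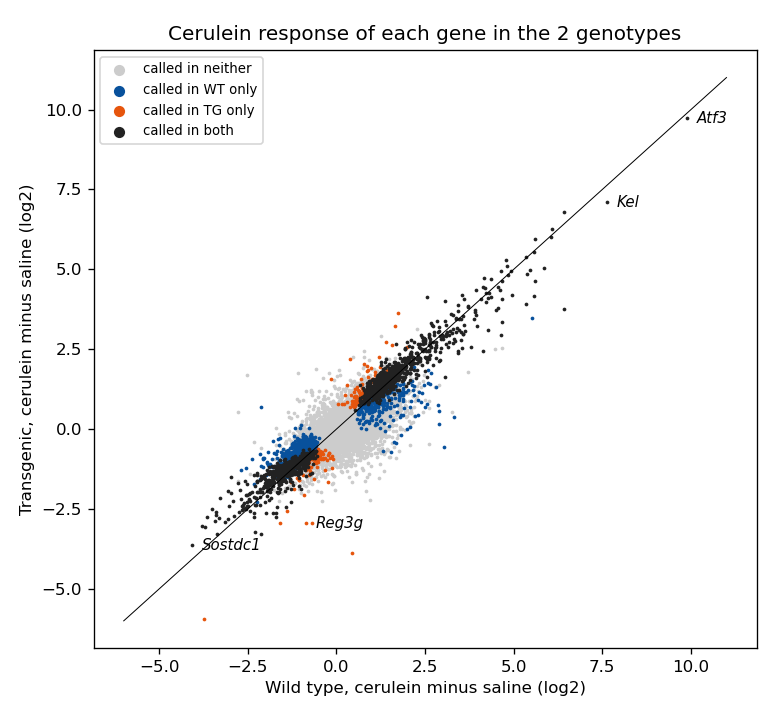
Log2 difference between cerulein and saline of each of 17338 genes in wild type (x axis) and transgenic mice (y axis), coloured by the genotypes in which limma called the gene, with the line of equality. Called genes lie along the line, from Sostdc1 (-4.08 and -3.63) to Atf3 (9.89 and 9.75).

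No gene passed limma's test of the difference between the responses (0 up and 0 down). At an unadjusted p below 0.05 there were 40 and 94, against 867 by chance for both directions together. Counts so far under chance mean that the p-values of this fit are not spread as chance alone would spread them. They are thus no evidence that the responses were alike. The test on simulated data did not cover this comparison, so its power is unknown. With slide in the model 0 rose and 1 was called lower in the transgenic response, Alox12e (adjusted p = 0.0369), a gene chosen after its values were seen; 201 and 212 had an unadjusted p below 0.05. The difference was 0.28 ± 0.54 for Egfr, -0.06 ± 0.66 for Btc, -0.26 ± 0.42 for Erbb2 and -0.62 ± 0.49 for Erbb3 (adjusted p = 1 for each). Camera called 8 lists. In the transgenic response ER stress genes were higher (0.48, adjusted p = 7.9e-06; slide-adjusted 0.33, within slides 0.57 and 0.48), as were ribosome biogenesis genes (0.37, 7.9e-06; 0.26, within slides -0.01 and 0.3), fibroblast markers (0.39, 7.9e-06; 0.29, within slides -0.04 and 0.65), antioxidant genes (0.22, 0.00414; 0.13, within slides -0.02 and 0.17) and heat shock proteins (0.33, 0.0469; 0.18 and not called, within slides -0.03 and -0.1). Reg family and acute phase genes were lower (-0.43, adjusted p = 3.78e-05; slide-adjusted -0.44, within slides 0.02 and -0.46), as were neutrophil markers (-0.42, 0.000203; -0.42, within slides -0.69 and -0.6) and lymphocyte markers (-0.49, 0.0107; -0.38 and not called, within slides -1.56 and 0.03). None held with an estimated correlation, where the Reg list gave adjusted p = 0.0684, neutrophil markers 0.801, ER stress, ribosome, fibroblast and antioxidant lists 0.874, lymphocyte markers 0.934 and heat shock proteins 0.947. No member of these lists was called, over all genes or adjusted over the list alone. The ER stress call was lost without transgenic saline replicate 2 (median 0.16), and the neutrophil call without wild type cerulein replicate 10 (-0.32) and with normexp (0.01). Without slide 2 the fibroblast (0.06), Reg (-0.35) and lymphocyte (-1.13) calls were lost and the heat shock median was -0.05. The heat shock call was lost in 11 fits that left out 1 array, and the lymphocyte call without transgenic saline replicate 2 (-0.49), transgenic cerulein replicate 14 (-0.19), wild type cerulein replicate 9 (-0.23) or 12 (-0.42), or wild type saline replicate 7, where the median was 0.14.

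**Figure D3:**
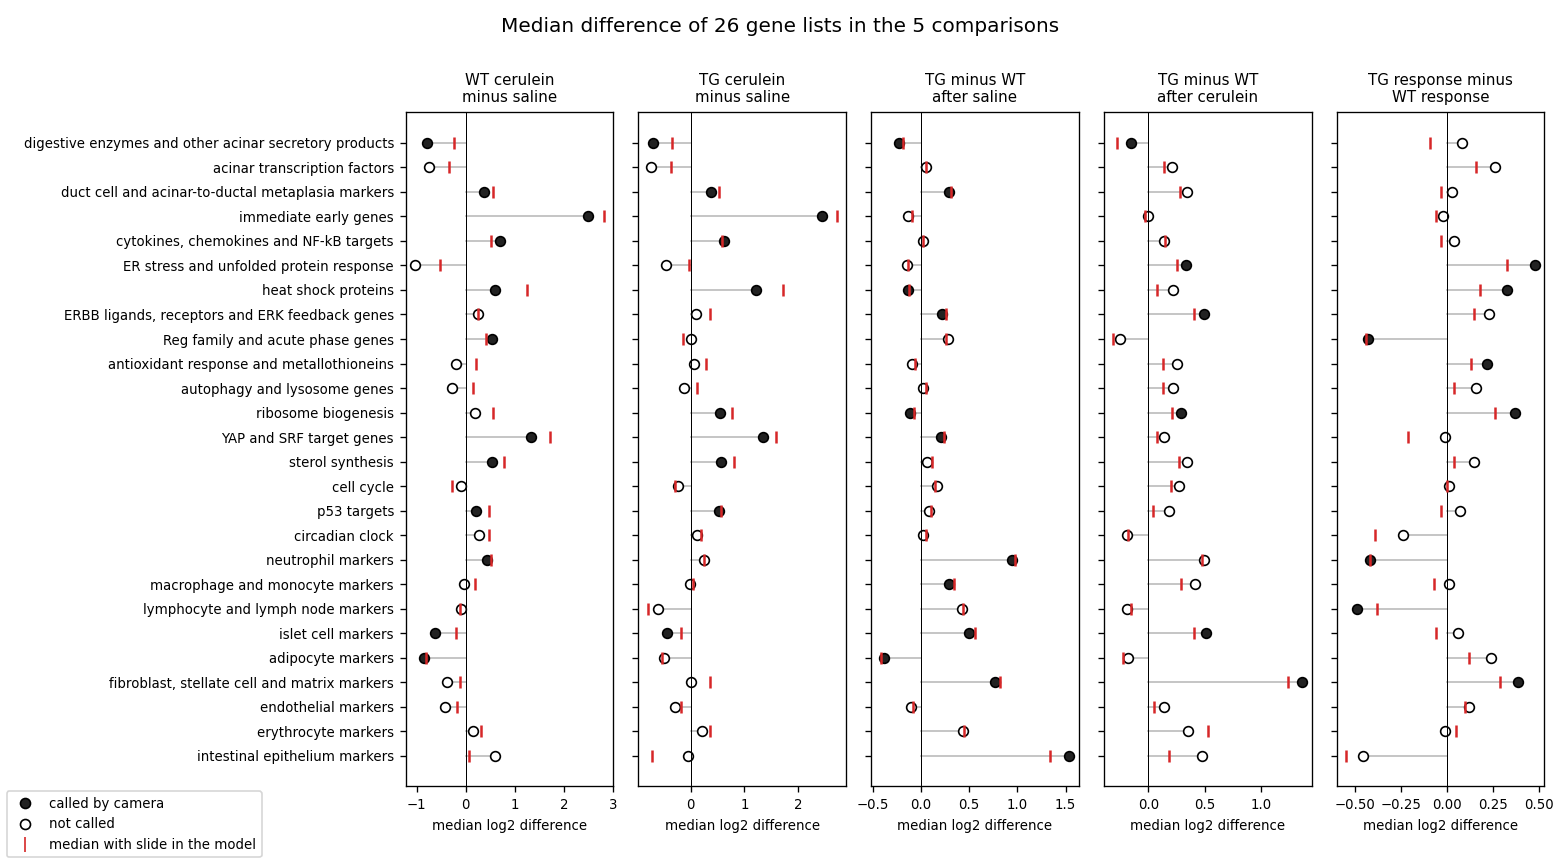
Median log2 difference (x axes) of the members of 26 gene lists (y axis) in 5 comparisons, each panel on its own scale. Filled points are lists called by camera with the preset correlation, open points are not called and red bars are slide-adjusted medians; immediate early genes have the highest medians in both cerulein responses (2.48 and 2.44), which were 1.27 and 1.62 with normexp.

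The comparison of transgenic with wild type mice after saline asks how the genotypes differed without cerulein (n = 3 and 4). Serpina6, which encodes the plasma corticosteroid carrier, was 133-fold higher in transgenic mice (7.05 ± 0.5, adjusted p = 1.14e-05). The plasma protein genes Ahsg, Alb and Fetub were higher by 5.93 ± 0.71 (adjusted p = 0.00296), 5.29 ± 0.56 (adjusted p = 0.000828) and 2.99 ± 0.43 (adjusted p = 0.0119). Otud7a, a deubiquitinase gene, was at least 3.48-fold higher (3.82 ± 0.36) and Tiam2, an exchange factor for RAC, at least 3.25-fold (2.81 ± 0.39). In each of these 6 genes all transgenic arrays lay above all wild type arrays. Slide-adjusted differences were 7.11 for Serpina6, 5.9 for Ahsg, 5.34 for Alb and 3.04 for Fetub. Within slides 1 and 3 Serpina6 differed by 5.99 and 7.58, Alb by 4.6 and 5.7, Ahsg by 2.12 and 7.49 and Fetub by 1.19 and 3.82. A second Serpina6 probe gave 7.26.

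After saline 13 genes were higher in transgenic mice and 0 lower by limma. At an unadjusted p below 0.05 there were 454 and 104, against 867 by chance for both directions together. With slide in the model these counts were 1066 and 705, so the lower ones are no evidence that the genotypes were alike. With slide in the model 39 were higher and 0 lower. The count was 4 and 6 without transgenic replicates 3 and 4 and 8 without wild type replicate 8, and the Fetub call was lost in each of these (lowest 2.63), the Tiam2 call in the first and second (lowest 2.53). Btc differed by 0.55 ± 0.48, Egfr by 0.25 ± 0.4, Erbb2 by -0.03 ± 0.31 and Erbb3 by 0.34 ± 0.36 (adjusted p = 1 for each; slide-adjusted 0.58, 0.31, -0.09 and 0.34). Of 2 called genes with several probes 0 had a probe with the opposite sign, and the same was true after cerulein.

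Camera called 12 lists between the genotypes after saline, and none held with an estimated correlation. Fibroblast, stellate cell and matrix markers were higher in transgenic mice (median 0.77, adjusted p = 1.65e-11; adjusted p = 0.372 with an estimated correlation; slide-adjusted 0.82, within slides 0.62 and 0.9). Of 16 members 0 were called over all genes and 4 adjusted over the list alone: Lum (1.71), Pdgfra (1.43), Pdgfrb (1.19) and Mmp2 (1.13), chosen after their values were seen. Neutrophil markers were higher (0.94, adjusted p = 2.14e-10; adjusted p = 0.152 with an estimated correlation; slide-adjusted 0.98, within slides 0.9 and 1.04), with 0 of 12 called and 6 adjusted over the list alone. Their median was 0.11 and called with normexp, and 0.09 and not called among probes above background on all arrays (adjusted p = 0.0745). Among the 6, S100a9 (3.9) and S100a8 (3.38) were highest, chosen after their values were seen. Islet markers were higher (0.5, adjusted p = 2.35e-05; adjusted p = 0.372 with an estimated correlation; slide-adjusted 0.56, within slides 0.87 and 0.34), with 0 of 20 called. Digestive enzymes were lower (-0.23, adjusted p = 1.69e-05, and 0.699 with an estimated correlation, slide-adjusted -0.19, within slides -0.24 and -0.15). Of 29 members 0 were called, and the list call was lost without transgenic replicate 2 (-0.02). The 75th percentile was 179 to 283 in transgenic and 152 to 237 in wild type saline arrays. This difference too cannot be told from the scaling.

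Intestinal epithelium markers were higher in transgenic mice after saline (median 1.54, adjusted p = 6.01e-05; adjusted p = 0.372 with an estimated correlation), with a median of 4.26 within slide 1 and -0.09 within slide 3, and -0.09 without transgenic replicate 2, whose mean over the list was 1.26. Transgenic cerulein replicate 14, on the same slide, had 0.88, and the other 13 arrays had -3.03 to -1.41. Duct markers (0.29, adjusted p = 0.00262; adjusted p = 0.395 with an estimated correlation; within slides 0.62 and 0.09) were not called without transgenic replicate 2. YAP and SRF targets were higher (0.21, adjusted p = 0.00534; adjusted p = 0.656 with an estimated correlation; slide-adjusted 0.24, within slides 0.12 and 0.17), a call lost without wild type replicate 7. Adipocyte markers were lower (-0.38, adjusted p = 0.00624; adjusted p = 0.372 with an estimated correlation; within slides -0.98 and -0.15), a call lost without wild type replicate 5 (-0.1). ERBB genes (0.22, adjusted p = 0.0098), macrophage markers (0.29, adjusted p = 0.0169), heat shock proteins (-0.14, adjusted p = 0.0332) and ribosome biogenesis (-0.11, adjusted p = 0.0438) were called, and none of these 4 with slide in the model (0.26, 0.34, -0.12 and -0.07). With an estimated correlation they gave adjusted p = 0.372, 0.372, 0.801 and 0.825. The ERBB call was also lost without transgenic replicate 3, the macrophage call without transgenic replicate 2 or wild type replicate 7, and the heat shock and ribosome calls without any 1 of transgenic replicate 2 and wild type replicates 7 and 8.

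The comparison of the genotypes after cerulein asks how they differed during pancreatitis (n = 4 and 4). Serpina6 was 61.9-fold higher in transgenic mice (5.95 ± 0.46, adjusted p = 3.97e-05), Alb 36.2-fold (5.18 ± 0.52, adjusted p = 0.000615) and Fetub 13.1-fold (3.71 ± 0.4, adjusted p = 0.000707). Matrix genes were higher as well: Postn, which encodes periostin, by 3.26 ± 0.49 (adjusted p = 0.0126), the proteoglycan gene Lum by 2.54 ± 0.39, Col1a1 by 2.51 ± 0.46, the gelatinase gene Mmp2 by 2.01 ± 0.28 (adjusted p = 0.0067), Col1a2 by 1.91 ± 0.34, Frem1 by 3.3 ± 0.52 (at least 2.28-fold) and Ccn2, a matricellular protein, by 1.15 ± 0.19. Cblif, which encodes intrinsic factor, was higher by 3.46 ± 0.55 with 1 of 4 wild type arrays above background, and Astn1 was lower (-1.89 ± 0.34, at least 1.2-fold). In all of these genes the groups did not overlap. Within slides 1, 2 and 3 Serpina6 differed by 5.76, 5.52 and 6.64, Alb by 5.66, 4.68 and 5.52, Fetub by 3.71, 3.63 and 3.87, Postn by 1.84, 4.1 and 3.56 and Mmp2 by 1.24, 2.16 and 2.52. Slide-adjusted differences were 5.92, 5.33, 3.74, 3.15 and 1.92 for these genes.

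**Figure D4:**
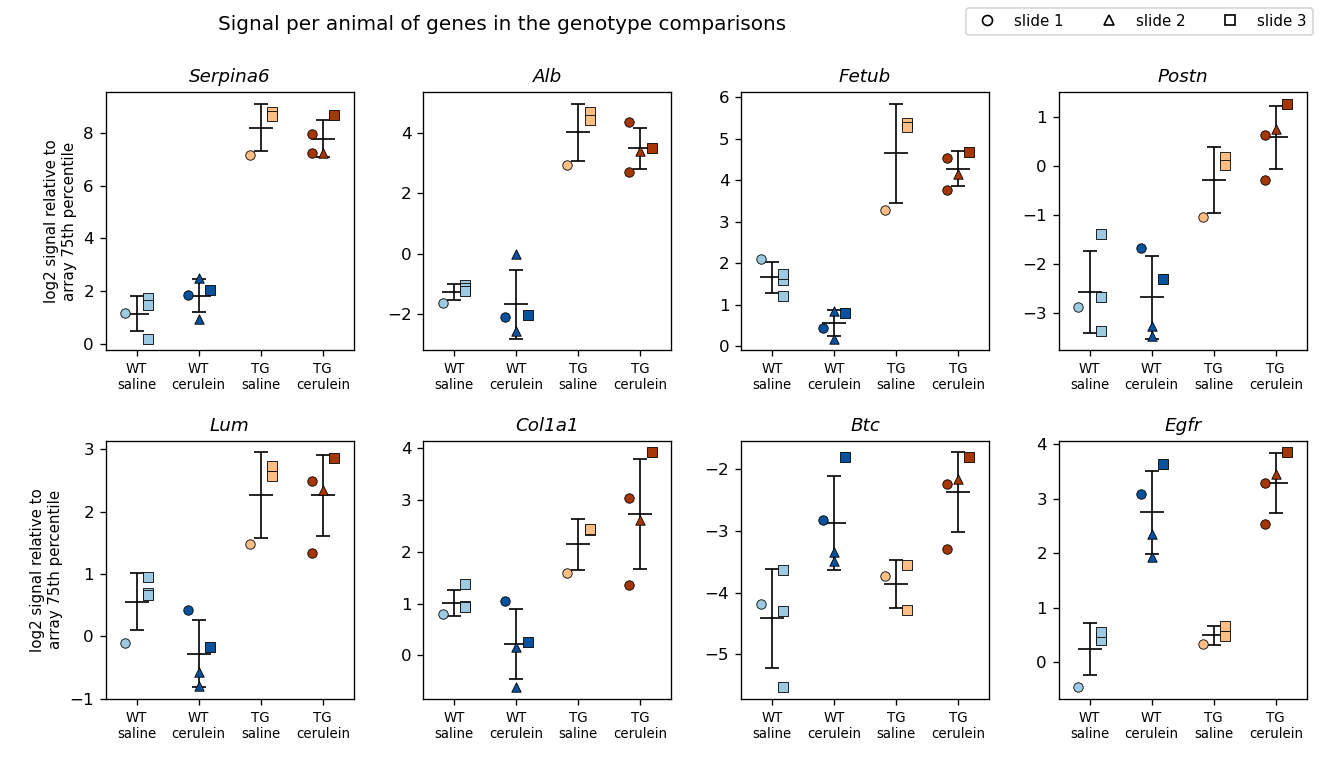
Log2 signal relative to the array's 75th percentile (y axes) of 8 genes in each animal, by group (x axis) and slide (shape), with bars for the group mean and standard deviation. Serpina6, Alb and Fetub of all 7 transgenic animals lie above all 8 wild type animals, whereas Btc and Egfr overlap between genotypes under each treatment.

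After cerulein 24 genes were higher and 1 was lower in transgenic mice; with slide in the model 89 were higher and 25 lower. The calls of Postn, Lum and Cblif were lost without transgenic replicate 14 or 15 or wild type replicate 11 or 12, and those of Ccn2 and Frem1 without these or wild type replicate 9 (lowest differences 2.99, 2.34, 3.03, 1.05 and 2.95). Those of Col1a1 and Col1a2 were lost without transgenic replicate 14, 15 or 16 or wild type replicate 10, 11 or 12 (lowest 2.12 and 1.61), and that of Astn1 without any array but transgenic replicate 15 (-2.13 to -1.72), whereas Serpina6, Alb, Fetub and Mmp2 were called in all 8 such fits. The count of higher genes was 10 without transgenic replicate 14 or 15, 11 and 12 without wild type replicates 11 and 12, and 44 without transgenic replicate 13; that of lower genes was 10 without transgenic replicate 16 and 0 without any wild type array. Between the treatments 6 genes were higher in transgenic mice after both, against 0.018 if calls were independent: Alb, Fetub, Serpina6, Lamc3, Mgp and Mmp3, the last 3 chosen after their values were seen. These calls also share each gene's estimate of spread, so they are not fully independent. Across genes the genotype differences after saline and after cerulein correlated at r = 0.519 (rho 0.476).

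Fibroblast, stellate cell and matrix markers were higher in transgenic mice after cerulein (median 1.36, adjusted p = 4.14e-17; adjusted p = 0.335 with an estimated correlation). Of 16 members 4 were called, or 11 adjusted over the list alone. The slide-adjusted median was 1.23, and within slides 1, 2 and 3 it was 0.52, 1.55 and 1.62. Islet markers were higher (0.51, adjusted p = 0.000552; slide-adjusted 0.4, within slides 0.31, 0.35 and 0.72), with 0 of 20 called and 2 adjusted over the list alone. ER stress genes were higher (0.33, adjusted p = 0.0166, slide-adjusted 0.25, within slides 0.28, 0.07 and 0.45). Digestive enzymes were lower (-0.15, adjusted p = 0.0166, slide-adjusted -0.28, within slides -0.09, -0.36 and -0.46). The 75th percentile was 265 to 529 in transgenic and 201 to 410 in wild type cerulein arrays, so the digestive difference cannot be told from the scaling. ERBB genes were higher (0.49, adjusted p = 0.04; slide-adjusted 0.4 and not called, within slides 0.25, 0.45 and 0.03), as were ribosome biogenesis genes (0.29, adjusted p = 0.04; slide-adjusted 0.21, within slides 0.1, 0.36 and 0.11). The islet, ER stress, digestive, ERBB and ribosome lists each gave adjusted p = 0.844 with an estimated correlation. Quantile normalization ended the ER stress, digestive and ERBB calls. Leaving out an array ended the ER stress call without transgenic replicate 15 or wild type replicate 9 or 11 (lowest 0.11), the digestive call without transgenic replicate 16 or wild type replicate 10 (highest 0.09), the ribosome call without transgenic replicate 15 or 16 or wild type replicate 9 or 11 (lowest 0.1) and the ERBB call without transgenic replicate 14 or 16 or wild type replicate 9, 10 or 11 (lowest 0.26). Endothelial markers had a median of 0.14 (adjusted p = 0.794) and neutrophil markers 0.49 (adjusted p = 0.0903). Reg family and acute phase genes had a median of -0.25 (adjusted p = 0.062), and camera called them lower with slide in the model (-0.31, adjusted p = 0.0209).

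The transgenic status was also read from Btc itself, for which the array has 1 probe. Its mean log2 level relative to the 75th percentile after saline was -3.86 ± 0.38 (SD) in 3 transgenic and -4.41 ± 0.8 in 4 wild type mice, with 2 and 1 arrays above background, and after cerulein -2.38 ± 0.64 and -2.87 ± 0.76 (n = 4 and 4). After cerulein Btc differed between genotypes by 0.49 ± 0.45 (adjusted p = 0.838; slide-adjusted 0.4, within slides 0.06, 1.24 and 0.01). The position of the probe relative to the transgene is not given in the sources used here, so the probe cannot tell whether the transgene was expressed. Egfr differed between genotypes after cerulein by 0.53 ± 0.37, Erbb2 by -0.29 ± 0.28 and Erbb3 by -0.28 ± 0.33 (adjusted p = 0.811, 0.843 and 0.858; slide-adjusted 0.45, -0.3 and -0.42).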

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

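The tests of the 3 patterns weighed below were all chosen after the patterns had been seen, while the counts of other splits of the arrays were planned.

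An array was singled out where its gap to the nearest of the 3 others of its group exceeded a share of the group's range that chance exceeds in about 1 in 20 groups. This happened in 19 of 264 groups of named genes, against 13.2 by chance, and in 0 of 9 measures of array quality. Wild type saline replicate 5 stood apart in 6 of the 19: Hspa1a (share 0.957; -1.73 against -3.49 to -3.42), Foxa2 (0.901), Ddx21 and Wdr43 (0.86 each), Trp53inp1 (0.848) and Egfr (0.837; -0.46 against 0.4 to 0.56). It is the only wild type saline array on slide 1, and the other 3 are on slide 3. In the other saline arrays Il1r2 stood apart in wild type replicate 8 (0.908) and Atf3 in wild type replicate 6 (0.853; -3.22 against -3.96 to -3.86). In wild type cerulein arrays they were Onecut1 in replicate 12 (0.916), Ccl7 (0.864) and Tac1 (0.851; -3.64 against 0.65 to 1.4) in replicate 11 and Gabarapl1 in replicate 10 (0.834). In transgenic cerulein arrays they were Dbp (0.947) and Ciart (0.873) in replicate 16, Sostdc1 (0.929), Slc7a11 (0.922) and Clec4d (0.837) in replicate 13, Krt20 in replicate 14 (0.833) and Gadd45a in replicate 15 (0.83).

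By camera's test of the difference between the genotypes' cerulein responses, 8 lists were called: ER stress (0.48), ribosome biogenesis (0.37), fibroblast markers (0.39), antioxidant genes (0.22), heat shock proteins (0.33), Reg family genes (-0.43), neutrophil markers (-0.42) and lymphocyte markers (-0.49). These calls rest on the preset correlation: with an estimated one no list was called (adjusted p from 0.0684 to 0.947), and with slide in the model heat shock proteins (adjusted p = 0.249) and lymphocyte markers (adjusted p = 0.0852) were not. Slide in the model also added a call, of digestive enzymes as lower in the transgenic response, where the median without slide was 0.08. Of 100 random splits of the arrays, the real one included, 37 called as many lists (8; the highest other had 17), so chance could not be excluded for this number. For single genes limma called 0 up and 0 down (40 and 94 at an unadjusted p below 0.05). Since each of 100 splits gives at least 0 (the highest other had 13), this count says nothing about chance.

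Among 12699 features without a gene symbol, which no comparison above used, 266 rose and 273 fell after cerulein in wild type mice and 210 and 215 in transgenic mice. Between genotypes 1 such feature was higher after saline and 3 after cerulein in transgenic mice.

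Other splits of the arrays were counted for each comparison, each fitted without slide. In transgenic mice 1 of the 35 splits gave as many cerulein genes, the real one (1422, where the highest other had 435). Between genotypes after saline again only the real split did (13, where the highest other had 1). A share of 1 in 35 is the smallest that these splits can give. It was not adjusted over the comparisons counted, and the splits ignore slide, so chance is not excluded for these counts. In wild type mice 2 of the 35 splits gave as many (2424; the highest other had 5458). That split sets the 4 arrays of slide 3 against those of slides 1 and 2, so it follows slide and scan day and points to a structure of the samples; with slide in the model the real comparison gave 2387 raised and 1351 lowered genes. Between genotypes after cerulein 3 of the 35 splits gave as many (25; the highest other had 4294), and the splits with the most genes largely follow slide 2. Chance was not excluded there without slide, and with slide in the model 89 genes were higher and 25 lower. For the number of lists called, 5 of 35 splits gave as many in the wild type response (12; highest other 15), 14 in the transgenic response (10; 14), 3 between genotypes after saline (12; 14) and 21 after cerulein (6; 13), so chance was not excluded for any of these numbers.

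The first pattern is that cerulein lowered 1448 genes in wild type and 593 in transgenic mice, a ratio of 2.44. With slide in the model the ratio was 0.934 (1351 against 1447), with 0.399 to 1.49 over fits without single arrays, and without slide 2 it was 0.812. The uneven spread of the groups over the slides, with 2 wild type and 1 transgenic cerulein array on a slide without saline arrays, is therefore a candidate explanation. A response that differs by genotype cannot be told apart within slide 3 alone (904 against 763, ratio 1.18), which holds 1 cerulein array of each genotype.

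The second pattern is the higher level of genes of liver secretory proteins in transgenic mice. Liver tissue in the samples would bring all abundant hepatocyte transcripts, yet the hepatocyte markers low in wild type pancreas differed by a median of -0.25 after cerulein (21 genes) and 0.26 after saline (23 genes). The 6 markers called after saline, of which 3 (Alb, Serpina6 and Fetub) were also called after cerulein, differed by medians of 3.04 after cerulein and 4.14 after saline. They were selected by this same difference, which makes their medians large. The test was run in more than one form. Over all 33 markers not called the medians were -0.1 and 0.23, but leaving out the called genes makes such medians small, so they add no evidence. The lowest difference of the 6 genes within any slide was 0.28. Genes called on the same arrays tend to keep their sign within slides, so this cannot exclude the spread over slides. Within single slides Alb differed by 4.6 or more and Serpina6 by 5.52 or more. Transcription of these genes by the transgenic pancreas itself stays open and was not tested.

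The third pattern is the higher level of fibroblast and matrix markers in transgenic mice after either treatment. A lower share of acinar cells would raise the markers of every other cell type alike. Fibroblast markers exceeded endothelial markers by 1.01 more in transgenic mice (0.79 after saline, 1.22 after cerulein), so these 2 lists did not rise alike. An exact permutation over 2450 splits within treatments gave p = 0.000408, the smallest they can give. The 2 lists were picked after the patterns had been seen and the splits ignore slide, so this p cannot weigh the explanation. Islet markers were higher (0.5 after saline, 0.51 after cerulein), as were neutrophil (0.94, and 0.49, not called), macrophage (0.29, and 0.41, not called) and duct markers (0.29, and 0.34, not called). The macrophage and duct calls after saline were lost without transgenic saline replicate 2, the array with high intestinal markers. The macrophage call was also lost with slide in the model. Digestive enzymes were lower (-0.23 and -0.15), which cannot be told from the scaling. Adipocyte markers were lower (-0.38, a call lost without wild type saline replicate 5, and -0.18, not called). Endothelial (-0.1 and 0.14) and lymphocyte markers (0.42 and -0.19) were not called. The markers of other cell types thus did not all move alike, but no list call held with an estimated correlation. A lower acinar share stays open. Within slides the lowest median difference of the fibroblast list was 0.52, on slide 1 after cerulein. There the list means were 1.47 and 2.33 in transgenic replicates 13 and 14 and 1.34 in wild type replicate 9. Within slides 2 and 3 the medians after cerulein were 1.55 and 1.62. After saline they were 0.62 and 0.9 within slides 1 and 3. The list was picked for its difference on these same arrays, so its sign within slides cannot exclude the spread over slides. More fibroblasts or more matrix transcripts per fibroblast stay open as explanations, and neither was tested.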

How the results depend on the processing

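The fits with normexp on the median signal, with features that lack a symbol and without slide 2 were chosen after the data were seen. Normexp on the mean signal was not run, since the files lack it, and camera was not run with slide as a random block. Of 148 results for named genes, 127 kept their direction and their side of the threshold with normexp, 144 with quantile normalization, 142 with no filter on dim probes, 138 with slide as a fixed block, 139 as a random block, 141 with the series table, 143 with the mean of a gene's probes, 147 with trend and robust eBayes, 136 with array weights, 142 with all features, 116 without slide 2, 113 within slide 3 and 7 within slide 1; of 101 with a probe above background on all arrays, all 101 did. Of 130 results for lists, 110 did with normexp, 113 with quantile normalization, 119 with no filter, 110 with the filter on all arrays, 105 with slide as a fixed block, 120 with the series table, 99 without slide 2 and 84 with an estimated correlation. With single arrays left out, 966 of 1148 results for genes and 960 of 1170 for lists did. The cause of the changes below was not tested, except where fewer arrays were used.

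With an estimated correlation the number of lists called fell to 1 in each cerulein response and to 0 in each of the other 3 comparisons. With normexp 2243 genes fell after cerulein in wild type and 949 in transgenic mice, 7 were higher in transgenic mice after saline and 2 were lower after cerulein, the Btc difference after saline was -0.03, and in the wild type response Cyp51 (-0.1) and Il1r2 (-0.26) changed sign. With quantile normalization 951 genes fell in transgenic mice, 808 fell in both genotypes, and between genotypes after cerulein 43 were higher and 3 lower and 3 lists were called. Between genotypes after cerulein limma called 0 lower genes with no filter (705 at an unadjusted p below 0.05), with the filter on all arrays (323), with trend and robust eBayes (438) and with all features (1233), and the series table gave 46 higher. With the filter on all arrays the neutrophil median in the wild type response was -0.53. With the mean of a gene's probes Nolc1 in the transgenic response was -0.17.

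With slide as a fixed block 2387 genes rose in wild type mice and 2635 rose and 1447 fell in transgenic mice, 2100 rose and 847 fell in both, 39 were higher in transgenic mice after saline and 89 higher and 25 lower after cerulein, and 1 gene had a lower transgenic response. The digestive enzyme median of the difference between responses was -0.09 with this block, and the list was called lower. Without the block its median was 0.08 and it was not called. With slide as a random block 2188 rose in wild type mice, 2416 rose and 1397 fell in transgenic mice, 1904 rose and 904 fell in both, 66 were higher and 2 lower after saline and 138 higher and 39 lower after cerulein. Within slide 1, which leaves 1 residual degree of freedom, limma called 0 genes up and 0 down in the wild type response (1366 and 368 at an unadjusted p below 0.05), 0 and 0 in the transgenic response (1117 and 767), 0 higher after saline (584) and 0 higher and 0 lower after cerulein (452 and 1181). Within slide 2 it called 0 higher and 0 lower after cerulein (954 and 415). Within slide 3 it called 1879 up and 904 down in wild type and 1858 up in transgenic mice, 4 higher after saline, and 2 higher and 0 lower after cerulein (1126 lower at an unadjusted p below 0.05). A group with 1 array on a slide was assumed to vary like the others.

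Array weights gave 2548 raised and 4545 lowered genes in wild type and 3175 and 4550 in transgenic mice, 401 higher and 161 lower after saline and 4 lower after cerulein. Without slide 2, which removes 3 of 8 cerulein arrays, 448 genes fell in wild type mice, 4 were higher and 0 lower between genotypes after cerulein (533 lower at an unadjusted p below 0.05), Btc there differed by -0.13, 5 lists differed between the responses, and the heat shock median of that difference was -0.05. With only the groups compared, which leaves fewer arrays to estimate the spread, 771 genes fell in wild type and 337 in transgenic mice, 5 were higher after saline, and 5 were higher and 0 lower after cerulein (291 lower at an unadjusted p below 0.05).

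With single arrays left out, lowered genes in wild type mice ranged from 657 (without saline replicate 6) to 3181 (without cerulein replicate 10). In transgenic mice raised genes ranged from 509 to 851 and lowered genes from 186 to 705, both lowest without saline replicate 3. Between genotypes after saline higher genes ranged from 4 (without transgenic replicate 3) to 12 and lists called from 6 (without transgenic replicate 2) to 15. After cerulein higher genes ranged from 10 (without transgenic replicate 14 or 15) to 44 (without transgenic replicate 13), lower genes from 0 (without any wild type array) to 10 (without transgenic replicate 16), and lists called from 3 (without wild type replicate 9 or 11) to 9. The lymphocyte median after saline ranged from -0.38 (without wild type replicate 7) to 1.08 and that of the difference between responses from -1.03 to 0.14 (without wild type saline replicate 7). The intestinal median after saline ranged from -0.09 (without transgenic replicate 2) to 2.62 and that of the difference between responses from -1.18 to 0.65 (without transgenic saline replicate 2).

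Further list calls were lost beyond those named in the report. With normexp these were islet and adipocyte markers in the wild type response, islet markers in the transgenic response, and ERBB, heat shock and ribosome lists between genotypes after saline. With the filter on all arrays they were Reg and adipocyte lists in the wild type response, the ERBB list after saline, ERBB and ribosome lists after cerulein, and heat shock and neutrophil lists in the difference between responses. With no filter they were neutrophil markers in the wild type response, the heat shock and ribosome lists after saline, the ERBB list after cerulein and the heat shock list in the difference. Without slide 2 they were Reg and neutrophil lists in the wild type response, islet markers in the transgenic response and the ribosome list after saline and after cerulein. The wild type neutrophil call and the heat shock call in the difference were also lost with quantile normalization and the series table, and the wild type Reg call with the series table.

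Calls of single genes were also lost. With normexp these included Clec4d in both cerulein responses, S100a8 in the wild type response, Otud7a and Tiam2 after saline, and Cblif, Frem1 and Astn1 after cerulein. With array weights they included S100a8 and S100a9 in the wild type response and Cblif, Frem1, Postn, Col1a1 and Astn1 after cerulein. With no filter and with all features Col1a1, Col1a2 and Astn1 were lost after cerulein, and with the mean of a gene's probes Ddx21 in both responses. Both without slide 2 and with only the groups compared, calls after cerulein were lost for Postn, Mmp2, Lum, Col1a1, Col1a2, Ccn2, Cblif, Frem1 and Astn1, and calls after saline for Fetub and Tiam2.

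Signal over background limits genes such as Tac1, Ccl7 and Cxcl1, for which no wild type saline array was above background, and Erbb4, which was not tested.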

Other observations

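All genes of this part except Egfr, Hbegf and Dusp5 were chosen after their values were seen. Outside the rule for named genes, Mgp and Lamc3, 2 genes of the matrix, were among those higher in transgenic mice after both treatments and with slide in the model. Mgp, which encodes matrix Gla protein, an inhibitor of calcification, was higher by 2.18 ± 0.29 after saline (adjusted p = 0.00786) and 2.41 ± 0.27 after cerulein (adjusted p = 0.000956), with slide-adjusted differences of 2.2 and 2.23. Lamc3, a laminin chain, was higher by 1.57 ± 0.24 (adjusted p = 0.0222) and 2.12 ± 0.22 (adjusted p = 0.000707), with slide-adjusted differences of 1.6 and 2.1. The matrix protease gene Mmp3 was also called higher after both, but no wild type array was above background, so no size is given.

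Within the ERBB list, the receptor gene Egfr and the ligand gene Hbegf rose after cerulein in both genotypes while others of the list fell. Of 23 measured members 5 rose and 4 fell in wild type mice, and 3 rose and 1 fell in transgenic mice. Dusp5, which encodes an ERK phosphatase, was among those that rose in wild type mice, so the ERK feedback genes went both ways. In wild type mice Etv5, an ETS transcription factor induced by ERK signals, fell by 1.57 ± 0.43 (adjusted p = 0.0249, slide-adjusted -1.17) and the ERK phosphatase Dusp6 by 1.09 ± 0.32 (adjusted p = 0.0369, slide-adjusted -0.56 and not called). Tgfa, an EGFR ligand, fell by 0.67 ± 0.18 in wild type mice (adjusted p = 0.0209) and by 1.09 ± 0.19 in transgenic mice (adjusted p = 0.0024). In transgenic mice Etv5 and Dusp6 differed by -1.38 ± 0.46 and -0.71 ± 0.35 (adjusted p = 0.0839 and 0.256).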
